A study of Homo sapiens with 12 samples.

How the data were processed

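Gene expression was measured by RNA sequencing in 12 libraries of the human oral squamous cell carcinoma line PE/CA-PJ41. Per the labels, 4 libraries came from untreated cells (control), 4 from cells given human plasma at 10% and 4 from cells given platelet-rich plasma (PRP) at 10%, with both treatments lasting 48 h. No culture time is given for the control libraries, so comparisons with control may not be at matched times. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with the RNeasy kit, polyadenylated RNA was captured, and libraries were made with the Watchmaker mRNA kit. Whether the counting used strand is not given in the sources used here.

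Salmon and the human build hg38 are named in the submitters' processing notes, without a version, and the transcript set is not given in the sources used here. The deposited file of each library lists, per the file headers, the transcript length, effective length, TPM (the share of transcripts) and estimated count of reads for each of 20375 genes. In 2 plasma libraries the TPM column is headed with the library's name. The deposited values use a decimal comma. TPM recomputed from the deposited estimated counts and effective lengths matched the deposited TPM for 20375 of 20375 genes in every library, within 1% plus 0.01 TPM. The files were deposited with 1 library each, and no pooling was found.

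The test written before the data were examined was a count model for estimated counts, with limma on log2 TPM where only TPM could be used. The automatic check of file units could not read decimal commas as counts, so the columns were registered without a count unit and no count model was run. The stated fallback became the main test, which is a departure from the plan. Estimated counts were still tested with limma's voom as an alternative chosen after seeing the data.

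The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(TPM + 1). It covered 12517 genes with at least 1 TPM in at least 4 libraries, with 1 term per group over all 12 libraries and 9 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. A TPM value is relative to all other genes of its library, and a change in effective length moves it even when the reads stay equal.

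Gene lists, 48 in number, were fixed before the data were examined, and 45 had at least 4 tested genes. They were tested with camera at a preset correlation between genes of 0.01, adjusted over 135 tests. The test was repeated with the correlation estimated per list, which called 0 of the 135. Named genes were chosen by a rule fixed in advance. It took the 10 largest changes in each direction among genes with adjusted p under 0.05, a mean of at least 5 TPM, a gene symbol and no overlap between the groups' libraries. It added up to 4 genes with the smallest adjusted p per called list, and a fixed set of genes of interest including CD274, VIM, CDH1 and the blood transcripts PPBP, PF4 and HBB. Of that set, 2 genes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

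The functions were tested on simulated data, drawn from the real means and library sizes with 200 genes changed. The cholesterol synthesis list was also raised 1.15-fold and counted as changed. In the version kept, unchanged genes had equal TPM in both groups. There, 202 calls in the simulated plasma comparison (12465 genes) held 13 false ones, or 6.4%. For the simulated PRP comparison with control (12456 genes) the false share was 7.3%, and for PRP against plasma (12461 genes) 5%. Far fewer genes were changed there than were called against control in the data, so these shares need not hold for the real calls. In the simulated plasma comparison 61.2% of genes changed 1.25-fold were recovered and 92% of those changed 1.5-fold. A first version held the share of reads equal instead, and 29.8% of its calls in the plasma comparison (12474 genes) were false, 32.9% in PRP against control (12470 genes) and 9.3% in PRP against plasma (12489 genes). In the plasma comparison 80.3% of the false calls had a shift in effective length over 0.1 on the log2 scale, against 13.5% of all genes. That version was set aside after its result was seen, because TPM differs by construction where reads are equal and effective lengths are not. Calls on TPM can therefore include such genes, and the test does not separate a change in transcript level from a change in the estimated length.

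Total estimated reads per library ranged from 36258955 to 41976136. A gene with 0 reads in plasma replicate 2, the library with the fewest reads, could be present at up to 0.0827 CPM, from a floor of 3 reads that covers counting error only. No pair of replicates agreed within sampling noise, the smallest chi-square per degree of freedom being 3.95. Genes with near-identical copies, such as SPRR2A, SPRR2D, SAA2, FAM25A, HBA1 and the metallothionein and HLA genes, share reads and are uncertain. Positions come from GENCODE 29 on GRCh38, the same assembly as hg38, matched by symbol for 161 of 166 named genes. That annotation release may differ from the one the submitters used.

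Alternatives were median centring, no filter, a filter at 5 TPM, a pseudocount of 0.1, only the 8 libraries compared, the replicate number as a block, each library left out in turn, and a fold limit. Alternatives added after seeing the data were voom with either of 2 scalings, leaving out the 3 libraries numbered 1, removing a trend with transcript length, and an exact permutation test of list means. Python 3.11.15 with pandas 2.3.3 was used for reading the files and matplotlib 3.10.9 for drawing.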

Results

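Messenger RNA levels were compared in PE/CA-PJ41 cells, an oral squamous cell carcinoma line, left untreated or cultured for 48 h with human plasma or with platelet-rich plasma (PRP), each at 10%, with n = 4 libraries per group. Errors beside TPM values are SD. Total estimated reads per library ran from 40166503 to 41531218 in control, 36258955 to 41946780 in plasma and 36943548 to 41976136 in PRP. Between 12231 and 12406 genes reached 1 TPM in a library.

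The first principal component, with 63.6% of the variance of the 1000 most variable genes, placed the control libraries apart from all treated ones. The mean distance between control and plasma libraries was 42.3 and between control and PRP libraries 45, against 24.2 within control. Plasma and PRP libraries lay 23.8 apart on average, close to the 23.1 within plasma and 23.4 within PRP. The second component held 7.6%, and the libraries numbered 1 scored highest on it in each group, at 6.90, 5.92 and 6.82. Mitochondrially encoded transcripts took the smallest share of reads in those libraries, 0.29% in control, 0.22% in plasma and 0.19% in PRP, against up to 0.97% in the others. As a gene list they were not called against control (camera adjusted p = 0.728 for plasma and 0.623 for PRP), with 0 of 13 genes past the threshold over all genes and 0 adjusted over the list alone.

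**Figure D1:**
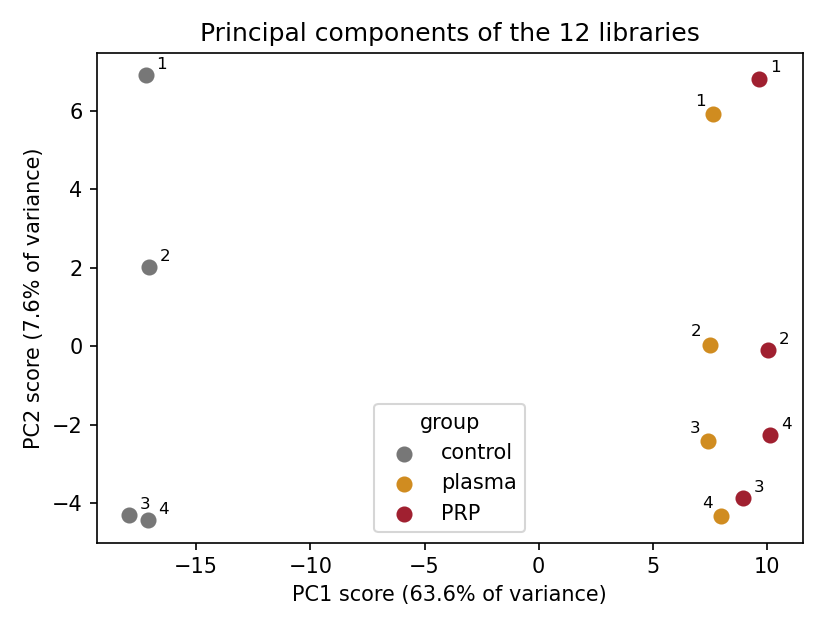
Scores of the 12 libraries on the first (63.6% of variance) and second (7.6%) principal components, coloured by group and numbered by replicate. Control libraries lie on the left and plasma and PRP libraries on the right.

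Plasma was first compared with untreated cells. Genes of the cholesterol synthesis list fell together, and inflammatory, interferon and mitosis genes were mostly higher. FDPS, which makes farnesyl diphosphate (chromosome 1, 155308748 to 155320666, GRCh38), went from 1281 ± 36.1 to 453 ± 30.7 TPM, a log2 change of -1.50 ± 0.04 (SE, adjusted p = 1.01e-10). IDI1 went from 182 ± 7.94 to 94.0 ± 1.73 TPM and SQLE from 256 ± 7.85 to 135 ± 6.40 TPM. Of 25 tested genes of the list, 23 fell and 0 rose, and 24 fell when adjusted over the list alone (camera adjusted p = 5.21e-17, and adjusted p = 0.331 with an estimated correlation). In fatty acid synthesis 13 of 15 genes fell, also adjusted over the list alone, among them ACLY, which makes cytosolic acetyl-CoA, from 649 ± 19.0 to 237 ± 30.6 TPM (camera adjusted p = 1.48e-06, and adjusted p = 0.529 with an estimated correlation).

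Inflammatory genes were higher with plasma. CXCL1, a neutrophil chemokine, went from 27.2 ± 4.24 to 104 ± 30.1 TPM, CCL20 from 3.84 ± 0.705 to 14.5 ± 2.55 and CCL2 from 28.5 ± 4.94 to 100.3 ± 31.1 TPM. Of 25 NF-kB inflammatory genes 19 rose and 4 fell, with 20 and 4 adjusted over the list alone (camera adjusted p = 6.71e-06, and adjusted p = 0.529 with an estimated correlation). The acute phase list had 11 of 15 genes higher and 1 lower, also adjusted over the list alone, with LCN2 at 42.1 ± 4.80 and 110 ± 19.0 TPM (camera adjusted p = 6.36e-05, and adjusted p = 0.529 with an estimated correlation). Of 34 interferon response genes 27 rose and 0 fell, and 28 rose adjusted over the list alone (camera adjusted p = 6.66e-10, and adjusted p = 0.529 with an estimated correlation). OAS1, an antiviral enzyme, went from 40.5 ± 4.01 to 79.5 ± 7.57 TPM.

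Among named genes the largest increase was in CYP26A1, which breaks down retinoic acid (chromosome 10, 93073475 to 93077890, GRCh38). It went from 2.82 ± 0.529 to 26.9 ± 1.23 TPM, a 9.55-fold ratio (log2 change 2.88 ± 0.10 SE, adjusted p = 2.65e-10). Of 14 retinoid and vitamin D targets 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.529 with an estimated correlation). Among mitosis genes 20 of 30 rose and 1 fell, also adjusted over the list alone, with PLK1, a mitotic kinase, at 60.0 ± 7.32 and 114 ± 5.82 TPM (camera adjusted p = 5.97e-07, and adjusted p = 0.618 with an estimated correlation). MKI67 was 34.6 ± 3.17 and 38.9 ± 8.62 TPM (adjusted p = 0.439). Nuclear genes of oxidative phosphorylation rose in 21 of 26 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 3.07e-07, and adjusted p = 0.331 with an estimated correlation). Keratinocyte differentiation genes rose in 13 of 28 cases and fell in 3, also adjusted over the list alone, with KRT13 at 284 ± 40.2 and 571 ± 51.4 TPM (camera adjusted p = 0.00166, and adjusted p = 0.529 with an estimated correlation).

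Of 10 targets of the aryl hydrocarbon receptor (AHR) 7 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0215, and adjusted p = 0.37 with an estimated correlation). CYP1A1 went from 116 ± 18.8 to 48.8 ± 2.22 TPM. Of 28 ATF4 targets 17 fell and 5 rose, with 19 and 5 adjusted over the list alone (camera adjusted p = 0.00166, and adjusted p = 0.621 with an estimated correlation). CHAC1, which degrades glutathione, went from 21.2 ± 2.82 to 5.26 ± 1.20 TPM. KATNBL1 went from 100.9 ± 11.6 to 35.5 ± 1.98 TPM, and its log2 change was -1.47 from TPM and -0.87 from reads, beside a shift of 0.57 in log2 effective length. Ribosomal protein genes fell in 23 of 40 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.705 with an estimated correlation). That call ended after median centring (adjusted p = 0.0957) and without the libraries numbered 1 (adjusted p = 0.0651). YAP and SRF targets fell in 17 of 23 cases and rose in 1, with 18 and 1 adjusted over the list alone (camera adjusted p = 0.000563). ERK pathway output genes fell in 11 of 19 cases and rose in 0 (camera adjusted p = 0.00469). Glycolysis genes rose in 9 of 18 cases and fell in 3 (camera adjusted p = 0.00469). For YAP and SRF, ERK and glycolysis the camera adjusted p was 0.629 each with an estimated correlation.

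Over all genes, 6173 of 12517 passed the adjusted threshold between plasma and control, 2544 higher and 3629 lower. With a log2 change of at least 1 the count was 172. The share of lower genes among the calls depended on scaling, at 58.8% as deposited and 45.9% after median centring.

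PRP was next compared with untreated cells, and 6652 genes passed, 2711 higher and 3941 lower, with 208 at a log2 change of at least 1. The lower share was 59.2% as deposited and 46% after median centring. FDPS went to 503.7 ± 13.3 TPM. Of 25 cholesterol synthesis genes 23 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.64e-11, and adjusted p = 0.37 with an estimated correlation). CYP26A1 reached 25.5 ± 2.63 TPM, a 9.05-fold ratio, and CXCL1 98.7 ± 4.32 TPM. CA9, a hypoxia-induced carbonic anhydrase, went from 0.704 ± 0.240 to 4.15 ± 0.206 TPM. The hypoxia list had 19 of 28 genes higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.00066, and adjusted p = 0.37 with an estimated correlation). Among the lower members was VEGFA, an angiogenic growth factor, from 74.0 ± 4.75 to 39.1 ± 3.17 TPM. These changes were not particular to PRP. With plasma 16 of 28 hypoxia genes were higher than in control and 7 lower, or 17 and 7 adjusted over the list alone. That list was called too (camera adjusted p = 0.00554, and adjusted p = 0.497 with an estimated correlation), and VEGFA fell to 34.95 ± 3.17 TPM. Between PRP and plasma the log2 difference of CA9 was 0.35, and 0 of 28 hypoxia genes passed over all genes.

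Mitosis genes rose in 22 of 30 cases with PRP and fell in 1, also adjusted over the list alone, with PLK1 at 123 ± 5.57 TPM (camera adjusted p = 1.2e-07, and adjusted p = 0.595 with an estimated correlation). Of 34 interferon response genes 23 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 8.66e-06, and adjusted p = 0.629 with an estimated correlation). SYP, a synaptic vesicle protein, went from 11.01 ± 0.805 to 2.26 ± 0.170 TPM, and DIO2, which activates thyroid hormone, from 14.6 ± 3.71 to 3.18 ± 1.03 TPM. CYP1A1 was 42.8 ± 1.64 TPM.

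**Figure D2:**
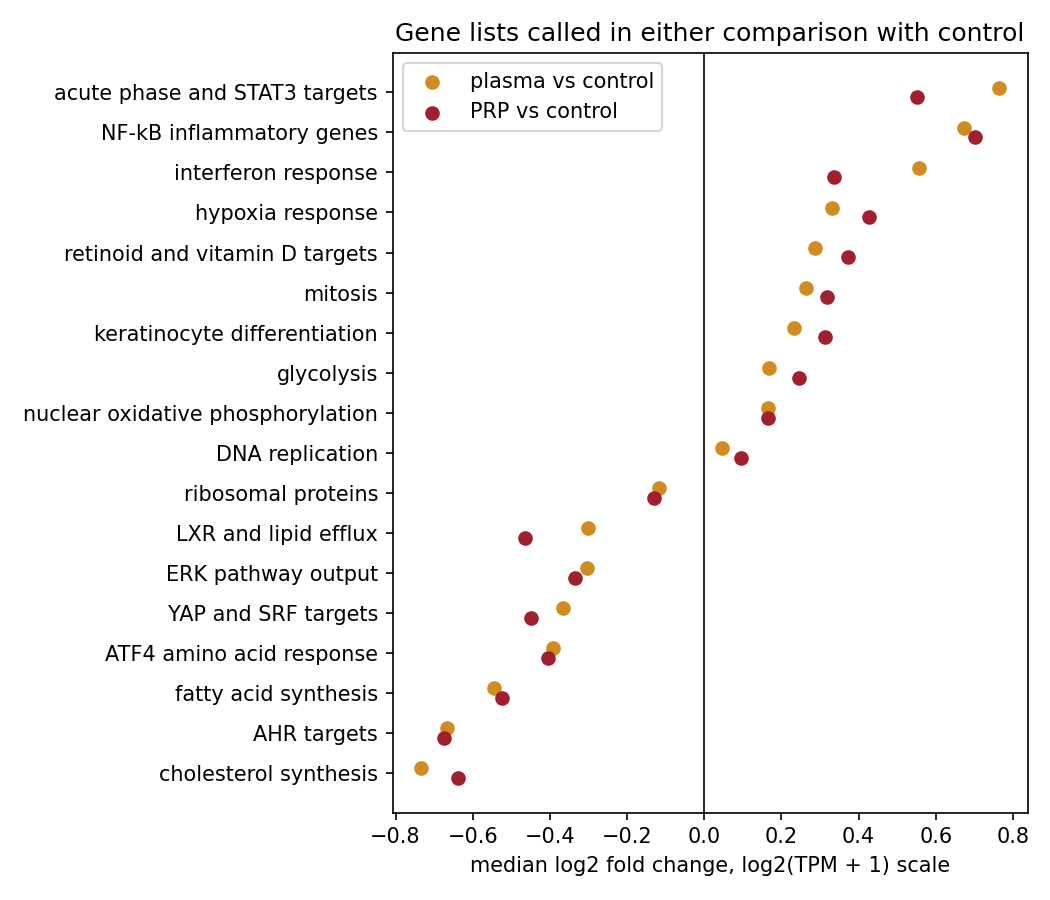
Median log2 fold change, on the log2(TPM + 1) scale, of the tested members of each gene list called in either comparison with control, for plasma and for PRP. Cholesterol synthesis has a median of -0.73 for plasma and -0.64 for PRP, and the targets of the aryl hydrocarbon receptor have -0.67 and -0.68.

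The changes with plasma and with PRP were compared across genes, which are not independent replicates. Their correlation was 0.948, against 0.496 for simulated unchanged groups that share controls and 0.857 with 2 controls set against each treatment. The covariance was 0.110 against a simulated 0.0055. Genes higher in both numbered 2269 and genes lower in both 3259. Simulated unchanged groups that share controls gave at most 0 shared calls in either direction over 100 simulations. Adjusted calls are rare in unchanged groups, so a count near 0 was nearly fixed in advance. It gives no expected overlap for groups that do differ from control. Lists of these sizes with no shared controls would share 551 and 1142.6 by independence, a value that leaves out the shared controls and so is not the one expected here. No gene was called in opposite directions (0 genes).

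PRP was then compared with plasma, and 8 genes passed with limma, all higher with PRP, while 999 genes had an unadjusted p under 0.05. Genes lower with PRP also passed in some alternatives, 5 of 16 with only the 8 libraries compared, 3 of 13 without control replicate 3 and 2 of 14 without control replicate 1. HMGCS1 (chromosome 5, 43289395 to 43313512, GRCh38), an early enzyme of cholesterol synthesis, was 94.0 ± 3.74 TPM with plasma, 119 ± 5.25 with PRP and 145 ± 4.83 in control (log2 difference 0.34 ± 0.04 SE, adjusted p = 0.00544). CYP51A1 was 108 ± 4.73, 138 ± 5.81 and 152 ± 4.90 TPM in the same order (adjusted p = 0.00544). These 2 genes passed in 21 of 21 alternatives that set no fold limit, with highest adjusted p of 0.0499 for HMGCS1 and 0.0325 for CYP51A1, and neither reached a log2 difference of 1. ACAT2, S100A2, ECM1 and CYP26B1 passed in 10, 18, 9 and 6 of the same 21 alternatives. CYP26B1 had a log2 difference of 0.45 from TPM and 0.15 from reads. Its level was 7.92 ± 0.350 TPM with plasma, 11.2 ± 1.30 with PRP and 11.1 ± 0.276 in control. In TPM, PRP thus lay near control for this gene, and plasma lay below both. Its log2 effective length shifted by -0.35 between PRP and plasma. Reads gave no call for it (voom adjusted p = 0.563 under median-of-ratios scaling). MMP9, a matrix protease, was 2.29 ± 0.531 TPM with plasma, 6.04 ± 1.17 with PRP and 0.348 ± 0.0728 in control (adjusted p = 0.00544). ENSG00000283977 was 0.156 ± 0.126, 2.26 ± 0.914 and 2.435 ± 0.776 TPM in the same order (adjusted p = 0.00937). For ENSG00000283977 too, PRP lay near control and plasma below both. MMP9 and ENSG00000283977 were chosen after their values were seen, and they passed in 19 and 16 of 20 alternatives. Without the 3 libraries numbered 1, only HMGCS1 and CYP51A1 passed, a count of 2. Leaving out control replicate 1 gave 14 genes, control replicate 3 gave 13, plasma replicate 2 and PRP replicate 3 gave 5 each, and plasma replicate 4 and PRP replicate 2 gave 4 each.

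Of 25 cholesterol synthesis genes 3 were higher with PRP than with plasma over all genes and 20 adjusted over the list alone (camera adjusted p = 2.79e-29, and adjusted p = 0.236 with an estimated correlation). By camera at the preset correlation 18 lists were called between PRP and plasma, and with an estimated correlation 0 were. Of the 18, 3 reached the smallest exact permutation p that 70 assignments allow, 0.0286. They were cholesterol synthesis, hypoxia and AHR targets, and the adjusted p of each was 0.0623. With an estimated correlation the camera adjusted p was 0.331 for hypoxia and 0.405 for AHR targets. The camera call of the AHR list ended without plasma replicate 4 (adjusted p = 0.074) and without PRP replicate 4 (adjusted p = 0.0787). The interferon list was among the 18, with negative differences in 32 of 34 genes (camera adjusted p = 1.42e-09, and adjusted p = 0.529 with an estimated correlation). Its exact permutation p was 0.143, with 0 of 34 genes past the threshold over all genes and 0 adjusted over the list alone.

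**Figure D3:**
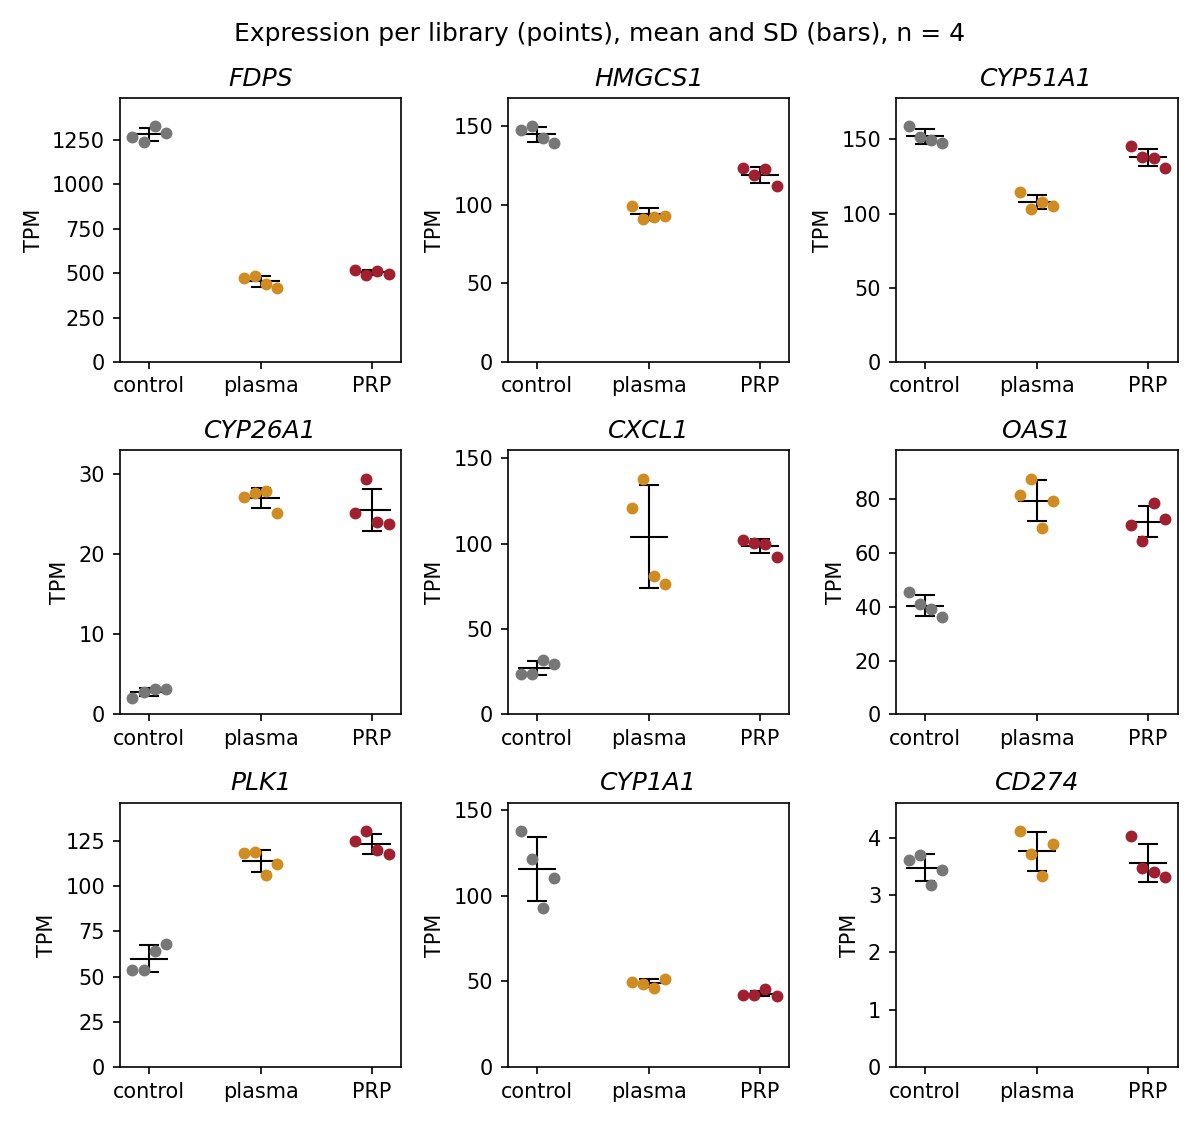
TPM of 9 genes in each library (points) with the group mean and SD (bars, n = 4), for control, plasma and PRP, on linear axes from 0. HMGCS1 and CYP51A1 lie between plasma and control in the PRP libraries, and CD274 overlaps between groups.

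CD274, which encodes PD-L1, was 3.48 ± 0.231 TPM in control, 3.76 ± 0.334 with plasma (adjusted p = 0.412) and 3.56 ± 0.326 with PRP (adjusted p = 0.831). CDH1 was 91.8 ± 16.1, 88.6 ± 10.9 and 87.9 ± 12.4 TPM, with adjusted p of 0.794 and 0.722 against control, and the sign of both differences turned with median centring, to 0.01 and 0.01. VIM rose from 45.8 ± 6.77 to 63.6 ± 2.57 TPM with plasma and 67.5 ± 4.43 with PRP (adjusted p = 0.000295 and 6.28e-05). Of 37 genes of the partial EMT list 13 rose and 15 fell with plasma, also adjusted over the list alone (camera adjusted p = 0.964). With PRP 15 rose and 15 fell, or 16 and 15 adjusted over the list alone (camera adjusted p = 0.561). Between PRP and plasma camera called the list as higher with PRP (adjusted p = 0.00584, and 0.629 with an estimated correlation). There 26 of 37 differences were positive, 0 genes passed over all genes, and the exact permutation p was 0.486. That camera call ended without plasma replicate 4 (adjusted p = 0.0618) and without PRP replicate 1 (adjusted p = 0.0612).

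Blood cell transcripts were examined because both additives come from blood. PF4 and HBB had 0 reads in every library, and the platelet transcript PPBP had 3 reads in PRP replicate 3 and 0 in the others. GP1BB, another platelet list member, was chosen after its values were seen. It had 13.7 estimated reads in plasma replicate 4, 9.06, 18.3 and 7.40 in PRP replicates 1, 2 and 4, and 0 in all other libraries. The summed platelet list was 14.6 ± 0.933 TPM in control, 16.3 ± 0.587 with plasma and 16.1 ± 1.16 with PRP. Most of that sum came from GNG11 (at most 8.99 TPM) and NRGN (at most 7.29 TPM). In control libraries GNG11 had 565 to 632 reads and NRGN 119 to 150, so the sum is a weak measure of platelet RNA. The exact permutation p, two-sided over 70 assignments, was 0.0571 for plasma against control, 0.143 for PRP against control and 0.771 for PRP against plasma. Adjusted over 9 such tests, the platelet values were 0.385, 0.385 and 0.771, and the smallest p this design can give is 0.0286. Erythroid and leukocyte sums gave exact permutation p from 0.143 to 0.771. The mean log2 value of the 6 tested leukocyte genes was higher than in control with plasma and with PRP, each at the smallest exact permutation p of 0.0286 (adjusted p = 0.0623). Of these genes 4 rose and 1 fell with plasma, and 2 rose and 0 fell with PRP, also adjusted over the list alone (camera adjusted p = 0.146 and 0.257, fry adjusted p = 0.00217 and 0.0127). Other members did not follow them. PTPRC, a transcript of all leukocytes that was below the filter, had 25 to 35 reads in control, 2 to 9 with plasma and 2 to 7 with PRP, and was chosen after its values were seen. Of the 20 leukocyte genes 6 had 0 reads in every library.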

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

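The values below are of 1 library set apart from the other 3 of its group by a fixed limit on the gap. The limit was applied to 627 groups of 4 values, and 29 exceeded it, no more than the 31.4 that chance gives on average.

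Total reads were 36258955 in plasma replicate 2 and 36943548 in PRP replicate 1, each below the other 3 libraries of its group. In control, CCL20 was 4.891 TPM and IGFBP7 44.91 TPM in replicate 2, and the mean log2 value of the hypoxia list was 4.239 in replicate 1.

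In plasma replicate 1, DUSP6 was 10.22, ABCG1 21.06, FADS2 28.59, GBP2 26.45 and MT1G 2.043 TPM, each above the other plasma libraries. RPL13 was 2576 TPM in plasma replicate 4.

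In PRP replicate 4, LRG1 was 15.54, TMEM265 14.08, AXL 29.31, KRT13 588.3, SPRR2D 6.399 and MT1F 8.65 TPM. The immediate early list had a mean log2 value of 4.048 there. In PRP replicate 3, CYP1A1 was 45.21, TGM2 0.4489, HLA-B 594.6 and BNIP3 37.13 TPM, and the leukocyte list had a mean log2 value of 2.231. In PRP replicate 2, PGAM1 was 818.5, SPRR1B 162.9, COX6C 496.7 and IRF7 25.78 TPM. In PRP replicate 1, FADS1 was 67.68 TPM and the immune checkpoint list had a mean log2 value of 4.657.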

How the results depend on the processing

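Voom, leaving out the libraries numbered 1, length correction, median-centred list tests and permutation of list means were chosen after seeing the data. The counts against control stayed within 1.5 times the reported count in every alternative except the fold limit, which gave 172 for plasma, 208 for PRP and 2 for PRP against plasma. Calls between PRP and plasma were few and moved more, to 4 without a filter, 16 with only the 8 libraries compared, 13 with voom on total library size and 2 without the libraries numbered 1. The cause was not tested. Leaving out each library in turn gave 5488 to 6181 calls for plasma, 5955 to 6598 for PRP and 4 to 14 for PRP against plasma.

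Gene list counts depended on the set test. With an estimated correlation they were 0, 0 and 0, with permuted list means adjusted over 135 tests 0, 0 and 0, and with fry 31, 28 and 5. A 4 against 4 permutation cannot go below 0.0286 before adjustment. Leaving out each library gave 16 to 19 lists for plasma, 16 to 18 for PRP and 15 to 20 for PRP against plasma. Among 84 list tests that were not called, 21 turned direction in at least 1 alternative, and in 1 of those alternatives the adjusted p was under 0.05, for mitochondrially encoded mRNAs between PRP and plasma without PRP replicate 1 (0.0347). Leaving out each library put the adjusted p of those mRNAs between 0.0027 (without plasma replicate 1) and 0.789 there, 0.232 and 0.963 for plasma and 0.191 and 0.96 for PRP. The partial EMT list turned with plasma under fry (0.355), median centring (0.958), length correction (0.928), without the libraries numbered 1 (0.841), with permuted means (0.454) and without 5 of the 12 libraries in turn, with 0.814 to 0.985 over all 12. With PRP it turned under fry (0.962) and permuted means (0.897) and without 0 of the 12 libraries, with 0.427 to 0.647 over all 12. The correlation of both treatments' changes was 0.857 with the controls split.

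Genes that were not called had differences near 0 whose sign turned. For CDH1 the log2 difference was 0.014 with plasma and 0.008 with PRP after median centring, and 0.021 and 0.011 with voom under median-of-ratios scaling. Leaving out each library gave -0.12 to 0.038 with plasma, -0.14 to 0.024 with PRP and -0.098 to 0.064 between them. CD274 with PRP was -0.011 without the libraries numbered 1 and -0.026 to 0.048 leaving out each library. MKI67 ran from -0.002 to 0.22 with PRP and -0.148 to 0.103 between PRP and plasma. The platelet sum between PRP and plasma ran from -0.5806 to 0.1782 TPM (0.00922 as a mean of log2 values), the erythroid sum with PRP from -0.1133 to 0.5543 TPM (-0.01758), and the leukocyte sum between PRP and plasma from -0.4317 to 2.084 TPM.

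With the replicate number as a block, calls were 6600, 7105 and 9, and lists 18, 19 and 21. The correlation of same-numbered libraries' deviations ran from -0.067 to 0.168 for plasma and control, 0.028 to 0.152 for PRP and control and 0.051 to 0.304 for PRP and plasma. Libraries matched their own number best in 2, 2 and 3 of 4 cases. The main test did not take the numbers as pairs. These matches alone do not exclude a structure along the numbers, and other values pointed to one. In each group libraries 1 and 4 differed more than libraries 3 and 4. The chi-square per degree of freedom was 32.6 and 3.95 in control, 25.55 and 4.76 in plasma, and 23.16 and 7.83 in PRP. The second principal component also followed the numbers. The source of this structure is not known, and the main test did not model it. The planned count-model tests and their scalings were not run.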

Other observations

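The tests without the libraries numbered 1, with the length trend removed, with voom, with permuted list means and over evenly mixed splits were chosen after seeing the data. CDH5, a cadherin of endothelial junctions, was 9.44 ± 3.68 TPM in control, 25.4 ± 2.76 with plasma and 24.6 ± 2.07 with PRP (adjusted p = 2.4e-05 and 2.55e-05). It was chosen after its values were seen. CD14, a lipopolysaccharide co-receptor, was 1.79 ± 0.743, 4.89 ± 0.824 and 5.49 ± 0.936 TPM in the same order (adjusted p = 0.000136 and 3.94e-05), and it too was chosen after its values were seen.

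Other splits of the 8 libraries compared were counted. For plasma against control 1 of 35 splits, the real one, gave 6173 genes, and the highest other gave 0. For PRP against control 1 of 35 gave 6652 genes, and the highest other gave 1. Both counts were thus above those of every other assignment of these libraries, and 1 of 35 is the smallest share possible. Since the libraries of a group may be technical replicates, a chance difference between cultures is not excluded. For PRP against plasma 2 of 35 splits gave at least 8 genes, so even a chance assignment of libraries cannot be excluded there. The other split gave 309 genes and set the libraries numbered 1 and 2 of both groups against those numbered 3 and 4, which points to a structure of the samples along the replicate numbers. The count with that number as a block was 9.

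As many gene lists as the 16 for plasma came from 8 of 35 splits (highest other 19), as many as the 17 for PRP from 4 of 35 (highest other 20), and as many as the 18 for PRP against plasma from 5 of 35 (highest other 19). Against control each other split with as many lists set 3 libraries of a group beside 1 of the other, which keeps part of the treatment difference, so these counts do not decide on chance. In the 18 splits that mix both groups evenly the most lists were 14 for plasma and 10 for PRP. For PRP against plasma evenly mixed splits reached 19 lists, so chance cannot be excluded for that count.

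More genes were lower than higher against control, 58.8% of the calls for plasma and 59.2% for PRP. Centring each library on its median gene gave 45.9% and 46%, but centring sets the median change near 0 by construction, so it does not show whether the scaling of TPM is the source. With voom on estimated counts the lower share was 55.1% for plasma and 56.6% for PRP under total library size, and 49.1% and 49.6% under median-of-ratios scaling. Which scaling is right stays open, since the labels name no spike-in.

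Oxidative phosphorylation genes are short, with a median transcript length of 1189 against 2563 bases over all tested genes, and changes fell with length (Spearman -0.154 across genes for plasma). After removing that trend the list's camera adjusted p was 3.3e-05 for plasma and 0.000154 for PRP, which argues against length as the whole cause. Ribosomal protein genes, also short, went the other way, with a median of -0.12. By fry the adjusted p of the oxidative phosphorylation list was 4.55e-06 for plasma and 3.28e-06 for PRP. Its exact permutation p was 0.0286 in both, the smallest possible (adjusted p = 0.0623). An effect of the treatments stays open as a hypothesis, limited by the loss of the camera call with an estimated correlation.

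The cholesterol synthesis list had a mean log2 value of 6.68 to 6.82 in plasma libraries and 6.88 to 6.97 in PRP libraries, with 3 of 25 genes past the threshold over all genes (fry adjusted p = 0.00092, exact permutation p = 0.0286, the smallest this design can give, and 0.0623 adjusted over 135 tests). If PRP acted on all genes alike as a smaller dose of plasma, the changes of other genes would be reduced too. Over 1452 other changed genes, of mean log2 change at least 0.5 in size, the median ratio of PRP to plasma changes was 1.097. Those genes as a whole thus showed no such reduction. The quartiles of that ratio over 23 cholesterol genes, taken without that size limit, were 0.69 and 0.84. Smaller mean log2 changes with PRP than with plasma also occurred for interferon response (0.346 and 0.507) and fatty acid synthesis (-0.476 and -0.573). Between PRP and plasma the exact permutation p of these lists was 0.143 and 0.229. Other lists changed more with PRP, such as hypoxia (0.309 and 0.204) and AHR targets (-0.648 and -0.558). Without the libraries numbered 1 the list's camera adjusted p at the preset correlation was 2.41e-30, while over all libraries the adjusted p was 0.236 with an estimated correlation. A difference in lipid supply between the additives is a candidate explanation that was not tested.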
